A study of Mus musculus with 80 samples.

How the data were processed

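The deposited file holds gene-level signal, normalized read counts per the authors' processing notes, with non-whole values for 50391 rows and 82 value columns. The submitters' processing notes name bcl2fastq 2.19, kallisto 0.44.0, sleuth and DESeq2, with GRCm38. The deposited sheet is titled for lung and a day that no sample has, while its column names match the labelled blood samples. Lung markers had a mean log2 value of at most 4.03 in any library, against 10.27 or more for B cell markers in the VarDR shams of day 30, so the columns were taken as the labelled blood samples. Whole blood was drawn by cardiac puncture into PAXgene tubes, globin was cleared, ribosomal RNA was depleted with Ribo-Zero and stranded total RNA libraries were made. Of the 82 columns, 80 matched a sample and were used, and 2 matched none and were left out. The 26 rows whose identifiers had become dates were left out (at most 0.471% of a column total), which left 50365 rows, 13129 of them 0 in every library. Of these, 49949 symbols are in GENCODE M21 on GRCm38, which gave the gene locations.

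Reads could not be recovered as whole numbers: of a column's values under 50 times its most common low step, 2.06 to 54.3% were whole multiples of that step within 0.01. Count models were therefore not used, and 2 alternatives built on them were replaced by a pseudocount of 0.1 and by quantile normalization. Column totals were 15.9 to 77.7 M (median 34.5), and 15637 to 27535 genes were above 0 (median 20804). Replicates of a group had Pearson r of 0.804 to 0.982 on log2 values, without duplicate libraries. The first 2 principal components held 24.7% and 8.9% of the variance. Xist was 8178 to 24174 in every library and Ddx3y at most 23, as in female mice.

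VarDR libraries of a day, irradiated and sham, had been scaled together: their medians of ratios differed by at most 0.0009 log2. Acute irradiated libraries exceeded their shams by 1.39-fold on day 2, 2.03-fold on day 3 and 1.93-fold on day 5 over the genes detected everywhere, while each of these groups spread by at most 0.073 log2. Each acute group therefore appears to have been scaled on its own, although the labels do not say so. The plan had been to use the values as deposited. This was changed after the data were seen: all columns were rescaled to equal medians of ratios over the 11349 genes above 0 in all 80 libraries, and the values as deposited became an alternative. Equal medians take the typical gene as unchanged, so a general rise or fall of most genes cannot be measured.

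Genes with a rescaled value of at least 10 in at least 3 libraries were tested (21101 genes). limma 3.58.1 in R 4.3.3 fitted log2(value + 1) with 1 mean per group, all 14 groups in 1 fit, and moderated variances with a trend and robust prior. The Benjamini-Hochberg adjustment was made within each comparison, and an adjusted p under 0.05 passed. The 7 comparisons with sham, 3 differences of acute and VarDR responses, 3 differences between days and 3 comparisons of shams were fixed before the data were examined, as were the 22 gene lists. Acute and VarDR exposures have separate shams. camera tested the lists with a preset correlation of 0.01 and with an estimated correlation, and fry was a further alternative. Shares of the signal and mean log2 list scores were compared by exact two-sided permutation tests with a Benjamini-Hochberg adjustment over 56 tests. Lists of liver (25 genes), kidney, skeletal muscle and skin markers (10 genes each) were added after the data were seen.

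The rule for naming genes was fixed beforehand and gives 605 gene results. From these 264 were selected by rank: the 3 highest and 3 lowest of each comparison with named genes, 7 p53 targets, and the 2 members with the smallest p of each list that passed. This narrowing was set after the data were seen, by rank alone and not by how the calls held. A few of the selected results are not reported here. Predicted genes (Gm and Rik names), pseudogenes and antigen receptor segments were not ranked. Alternatives fixed beforehand were no filter, a mean value of at least 1, only the compared groups, removal of haemoglobin and mitochondrial genes, leaving out each library, camera with an estimated correlation, and fry. Added after the data were seen were quantile normalization, a pseudocount of 0.1, the values as deposited, liver covariates (score and share), leaving out libraries with over 0.5% of signal in liver markers, and library weights.

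The fit was tested on simulated data with 200 of 21101 genes changed in irradiated libraries. Against sham it recovered 4.48 to 14.9% of 1.5-fold changes, 22.4 to 43.3% at 2-fold and 43.9 to 63.6% at 4-fold, without wrong signs. Unchanged genes were 2.78 to 8.62% of its calls, but relabelled real shams gave up to 1054. In response differences it recovered 12.8 to 22.4% at 2-fold. On VarDR day 2 all 3 list tests called only a shifted list. This cannot rank them on real lists, where preset, estimated and fry tests passed 11, 4 and 6. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.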

Results

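To describe the whole-blood transcriptome of female C57BL/6 mice exposed to a falling dose rate that simulates internal caesium (VarDR) or to an acute exposure, 80 libraries in 14 groups were compared: 38 from irradiated mice and 42 from shams of the same day and exposure type. VarDR mice had received 2 Gy by day 2 (n = 5), 2.8 Gy by day 3 (n = 6), 4.1 Gy by day 5 (n = 6) and 9.7 Gy by day 30 (n = 6). Acute mice received 2 Gy and were bled on day 2 (n = 6), 2.8 Gy for day 3 (n = 3) and 4.1 Gy for day 5 (n = 6). Each sham group had 6 mice, and each library came from a different animal. Values in parentheses after a gene are log2 differences ± standard error from limma, with q the Benjamini-Hochberg adjusted p over 21101 genes. Levels are rescaled read counts, mean ± SD. For each gene list the number of measured members past q = 0.05 is given out of all measured, then those past it when adjusted over the list alone, the median log2 difference (and that after quantile normalization where it moved over 1.5-fold in VarDR comparisons), and the camera q over 22 lists with a preset correlation of 0.01 and with an estimated one. The comparisons, the 22 lists and the rule naming genes were fixed before the data were examined.

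To find what the libraries were made of, the shares of the total signal held by 7SL RNA, haemoglobin genes and the mitochondrial ribosomal RNA mt-Rnr2 were compared by exact two-sided permutation tests, adjusted with Benjamini-Hochberg over 56 tests. The 7SL share, the RNA core of the signal recognition particle, fell in all 3 acute groups: 25.8 ± 4.76 against 39.8 ± 7.35% (mean ± SD) on day 2 (exact p = 0.00433, adjusted p = 0.0101), 20.6 ± 1.73 against 47.5 ± 5.87% on day 3 (exact p = 0.0119, the smallest that 84 arrangements can give, adjusted p = 0.0185) and 18.4 ± 7.69 against 47 ± 3.4% on day 5 (exact p = 0.00216, adjusted p = 0.0055). After VarDR it fell on day 3 (39.7 ± 8.02 against 50.9 ± 3.52%, exact p = 0.00649, adjusted p = 0.013) and rose on day 30 (56.9 ± 2.56 against 42 ± 4.39%, exact p = 0.00216, adjusted p = 0.0055). Haemoglobin genes held 0.499 ± 0.36 against 5.64 ± 2.3% on acute day 2 (exact p = 0.00216), 0.0595 ± 0.00755 against 5.71 ± 1.47% on day 3 (exact p = 0.0119) and 3.46 ± 1.47 against 5.7 ± 0.748% on day 5 (exact p = 0.00649). The mt-Rnr2 share was 3.25 ± 0.744 against 1.39 ± 0.255% on acute day 2 (exact p = 0.00216), 2.26 ± 0.233 against 1.54 ± 0.289% on day 3 (exact p = 0.0119), 5.25 ± 5.77 against 1.55 ± 0.339% on day 5 (exact p = 0.0303) and 2.18 ± 0.415 against 1.61 ± 0.346% on VarDR day 5 (exact p = 0.0238), with adjusted p at most 0.0447; the other VarDR days did not pass.

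To find which blood transcripts had changed 2 days into the falling dose rate, 5 mice given 2 Gy were compared with 6 shams. Of 21101 genes, 690 passed an adjusted p of 0.05 (533 higher, 157 lower, or 2058 with library weights). 283 higher and 61 lower changed over 2-fold (median of all genes −0.04). The p53 targets, genes switched on by DNA damage, rose in 13 of 26 (15 list alone, median 0.97, camera q = 4.22e-24, and 3.71e-16 estimated). They included the cell cycle inhibitor Cdkn1a (206 ± 33.5 against 26.7 ± 16.2 in shams, 3.10 ± 0.60, q = 3.10e-04), the AKT repressor Phlda3 (2.15 ± 0.27, q = 9.01e-08), Ccng1 (1.44 ± 0.12, q = 1.02e-14) and Bax (1.16 ± 0.13, q = 7.70e-09) and the p53 ligase Mdm2 (0.51 ± 0.14, q = 0.0153) and Aen (1.12 ± 0.24, q = 8.96e-04), while Eda2r (1.02 ± 0.80, q = 0.678) did not pass. Cdkn1a lies on chromosome 17 (29090976–29100727), Phlda3 on chromosome 1 (135766119–135769136) and Ccng1 on chromosome 11 (40748552–40755311), in GRCm38 coordinates. Highest were Trp53cor1 (3.57 ± 0.72, q = 5.12e-04), a long noncoding RNA next to Cdkn1a, then Cdkn1a and Chrne (3.04 ± 0.80, q = 0.0134); lowest were Rag1 (−4.60 ± 0.87, q = 2.13e-04), Klk1 (−3.96 ± 0.73, q = 1.14e-04) and Exosc6 (−3.87 ± 1.07, q = 0.0224), where Rag1 cuts antigen receptor genes in lymphocyte precursors.

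B cell markers fell in 18 of 23 (21 list alone, median −0.89, camera q = 3.01e-26, and 0.00971 estimated). These included Cd79a (−0.94 ± 0.20, q = 8.76e-04), part of the B cell receptor complex. MHC class II genes, which present antigen, fell in 10 of 11 (11 list alone, median −0.92, camera q = 1.96e-20, and 0.00452 estimated). Examples were Cd74 (−0.92 ± 0.17, q = 2.07e-04) and H2-Ob (−0.97 ± 0.19, q = 3.27e-04). Platelet markers rose in 16 of 18 (17 list alone, median 1.49, camera q = 2.37e-38, and 0.00211 estimated). Members were the platelet tubulin Tubb1 (1.71 ± 0.24, q = 2.32e-06) and integrin Itgb3 (1.78 ± 0.28, q = 9.26e-06). Mature neutrophil markers rose in 3 of 15 (9 list alone, median 1.04, camera q = 5.64e-11, but 0.0587 estimated). Among them were Csf3r (1.16 ± 0.25, q = 0.00117) and Mmp9 (1.04 ± 0.25, q = 0.00405). Monocyte markers rose in 1 and fell in 2 of 15 (1 higher and 6 lower list alone, median −0.39, camera q = 0.00309, but 0.372 estimated): F13a1 (0.87 ± 0.21, q = 0.00643) rose and Adgre4 (−0.72 ± 0.20, q = 0.0168) fell. NK and cytotoxic markers (14 list alone, median 0.86, camera q = 7.80e-12, but 0.105 estimated), T cell markers (median 0.36, camera q = 1.64e-05, but 0.43 estimated), red cell markers (median −0.74, −0.49 after quantile, camera q = 5.39e-05, but 0.524 estimated), haemoglobin genes (median −0.78, −0.41 after quantile, camera q = 0.027, but 0.43 estimated) and ribosomal protein genes (median −0.30, camera q = 5.35e-12, but 0.372 estimated) passed as groups without a single member past the threshold over all genes. The DNA repair genes, plasma cell markers, immature neutrophil granule genes, eosinophil and basophil markers, interferon-stimulated genes, NF-kB genes, cell cycle genes, NRF2 genes, mitochondrially encoded genes, lung cell markers and heart muscle markers did not pass (camera q 0.0979–0.917). Without VarDR day 2 replicate 1 the count was 452 (391 higher, 61 lower), and leaving out 1 library ended the calls of Chrne, Exosc6, Mdm2 and Adgre4.

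To find which transcripts differed at day 3 of the falling dose rate, 6 mice given 2.8 Gy were compared with 6 shams. Of 21101 genes, 2186 passed an adjusted p of 0.05 (1081 higher, 1105 lower). 469 higher and 545 lower changed over 2-fold (median of all genes −0.03). p53 targets rose in 15 of 26 (19 list alone, median 0.90, camera q = 2.26e-20, and 1.33e-14 estimated). These included Cdkn1a (261 ± 69 against 34 ± 28.7 in shams, 3.24 ± 0.57, q = 2.93e-05), Phlda3 (2.72 ± 0.26, q = 1.70e-12), Ccng1 (1.55 ± 0.11, q = 1.74e-17), Bax (1.44 ± 0.13, q = 1.27e-13), Aen (1.41 ± 0.22, q = 4.19e-06) and Mdm2 (0.57 ± 0.13, q = 0.0012) and the ectodysplasin receptor Eda2r (3.27 ± 0.76, q = 0.00158). The T cell costimulatory ligand Tnfsf4 (4.67 ± 0.68, q = 6.55e-07), on chromosome 1 (161395409–161418410), was the highest, followed by Eda2r and Mrgpra2a (3.27 ± 1.05, q = 0.0298); the kallikrein Klk1 (−4.60 ± 0.69, q = 1.29e-06), AA465934 (−4.30 ± 1.48, q = 0.0478) and Pgk1-rs7 (−3.35 ± 0.97, q = 0.0127) were the lowest. Plasma cell markers rose in 2 of 13 (5 list alone, median 0.77, camera q = 0.00192, but 0.0741 estimated). Examples were the antibody chains Igha (2.61 ± 0.38, q = 7.53e-07) and Jchain (2.10 ± 0.32, q = 1.30e-06). DNA repair genes fell in 5 of 31 (5 list alone, median −0.13, camera q = 0.00762, but 0.0518 estimated). Members were the Fanconi genes Fancd2 (−1.52 ± 0.32, q = 5.14e-04) and Fanci (−1.05 ± 0.26, q = 0.00279).

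B cell markers fell in 13 of 23 (16 list alone, median −0.69, camera q = 4.50e-11, but 0.131 estimated). Among them were Ighd (−0.97 ± 0.21, q = 6.96e-04) and Bank1 (−0.93 ± 0.21, q = 7.47e-04). MHC class II genes fell in 8 of 11 (10 list alone, median −0.69, camera q = 1.48e-09, but 0.0759 estimated). These included H2-Aa (−0.85 ± 0.17, q = 3.03e-04) and H2-Ab1 (−0.76 ± 0.16, q = 6.19e-04), neither past 0.05 after quantile normalization (−0.59 and −0.53). Platelet markers rose in 17 of 18 (18 list alone, median 1.53, camera q = 6.96e-30, and 0.00977 estimated). Examples were Itga2b (2.03 ± 0.26, q = 3.59e-08) and Itgb3 (2.05 ± 0.26, q = 5.47e-08). Mature neutrophil markers rose in 12 of 15 (14 list alone, median 1.52, camera q = 1.57e-15, and 0.0203 estimated). Members were Mmp9 (1.74 ± 0.23, q = 1.39e-07) and Csf3r (1.67 ± 0.24, q = 4.73e-07). Red cell markers fell in 14 of 24 (20 list alone, median −1.27, −0.64 after quantile, camera q = 8.34e-13, but 0.144 estimated). Among them were the haem synthesis enzyme Alas2 (−1.71 ± 0.33, q = 1.04e-04) on chromosome X (150547375–150570638) and Hemgn (−1.49 ± 0.33, q = 8.14e-04), where Alas2 did not pass after quantile normalization (−0.22, adjusted p = 0.545 by limma). Haemoglobin genes fell in 2 of 7 (5 list alone, median −1.09, −0.67 after quantile, camera q = 0.00138, but 0.158 estimated). These included Hbb-bt (−1.44 ± 0.44, q = 0.0214) and Hbb-bs (−1.28 ± 0.41, q = 0.0309), near-identical copies whose reads overlap, so each is uncertain; neither passed after quantile normalization (−0.67 and −0.19, adjusted p = 0.327 and 0.838 by limma). T cell markers rose in 4 of 23 (6 list alone, median 0.38, camera q = 1.59e-05, but 0.299 estimated). Examples were Bcl11b (0.68 ± 0.19, q = 0.00945) and Cd4 (0.68 ± 0.22, q = 0.0366). NK and cytotoxic markers rose in 5 of 15 (7 list alone, median 0.65, camera q = 1.01e-06, but 0.175 estimated). Members were Il2rb (1.05 ± 0.25, q = 0.00208) and Tbx21 (0.90 ± 0.27, q = 0.0172).

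Interferon-stimulated genes moved both ways on VarDR day 3: the list rose in 1 and fell in 8 of 26 (1 higher and 9 lower list alone, median −0.30, camera q = 1.85e-04, but 0.158 estimated). Among them were Irf7 (−1.62 ± 0.27, q = 1.39e-05) lower and Ifit2 (1.07 ± 0.18, q = 1.68e-05) higher. NF-kB genes rose in 3 of 16 (3 list alone, median 0.43, camera q = 0.00191, but 0.131 estimated). These included Il1b (1.57 ± 0.33, q = 5.37e-04) and Icam1 (0.57 ± 0.14, q = 0.002). Cell cycle genes fell in 6 of 30 (10 list alone, median −0.65, camera q = 4.99e-08, but 0.138 estimated). Examples were Nusap1 (−1.67 ± 0.37, q = 0.00102) and Kif11 (−0.88 ± 0.23, q = 0.00551). Ribosomal protein genes fell in 16 of 54 (19 list alone, median −0.32, −0.12 after quantile, camera q = 6.98e-12, but 0.226 estimated). Members were Rplp0 (−1.22 ± 0.20, q = 7.63e-06) and Rps29 (−0.86 ± 0.19, q = 7.89e-04). Lung cell markers rose in 2 of 7 (3 list alone, median 1.27, camera q = 0.041, but 0.158 estimated). Among them were the surfactant genes Sftpa1 (2.25 ± 0.72, q = 0.0301) and Sftpb (2.07 ± 0.72, q = 0.0496). Camera passed 16 of the 22 lists, and the others had q 0.0621–0.838. Leaving out 1 library ended the calls of Mrgpra2a, AA465934, Cd4, Tbx21, Hbb-bt, Hbb-bs, Sftpa1 and Sftpb.

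To follow the response to day 5 of the falling dose rate, 6 mice given 4.1 Gy were compared with 6 shams. Of 21101 genes, 1854 passed an adjusted p of 0.05 (1141 higher, 713 lower, or 1103 with library weights). 685 higher and 313 lower changed over 2-fold (median of all genes 0.10). p53 targets rose in 15 of 26 (19 higher and 1 lower list alone, median 0.90, camera q = 3.71e-17, and 6.98e-13 estimated). These included Cdkn1a (347 ± 68.9 against 38.1 ± 29.1 in shams, 3.96 ± 0.57, q = 5.97e-07), Phlda3 (3.01 ± 0.26, q = 2.13e-14), Ccng1 (1.34 ± 0.11, q = 2.13e-14), Bax (1.04 ± 0.13, q = 9.68e-09), Aen (0.91 ± 0.22, q = 0.00362) and Mdm2 (0.76 ± 0.13, q = 1.22e-05). The highest was Eda2r (105 ± 53.6 against 4.88 ± 7 in shams, 4.95 ± 0.76, q = 1.96e-06) on chromosome X (97333840–97377216), then Cnn1 (4.60 ± 0.77, q = 9.06e-06) and Tnfsf4 (4.35 ± 0.68, q = 2.62e-06); the lowest were Prg2 (−4.33 ± 0.92, q = 5.72e-04), a granule protein of eosinophils, Klk1 (−4.10 ± 0.69, q = 1.08e-05) and Rag1 (−3.43 ± 0.83, q = 0.00309). DNA repair genes fell in 2 of 31 (1 list alone, median −0.30, camera q = 8.92e-04, and 0.00555 estimated). Examples were Parp1 (−0.99 ± 0.11, q = 7.35e-10) and Ercc1 (−0.64 ± 0.22, q = 0.0492). B cell markers fell in 22 of 23 (22 list alone, median −1.44, camera q = 1.08e-51, and 1.71e-04 estimated). Members were Ighd (−2.08 ± 0.21, q = 4.40e-11) and Cd79a (−1.75 ± 0.19, q = 1.62e-10). MHC class II genes fell in 11 of 11 (11 list alone, median −1.38, camera q = 7.25e-32, and 1.71e-04 estimated). Among them were their master regulator Ciita (−1.64 ± 0.19, q = 2.55e-09) and H2-Ob (−1.51 ± 0.18, q = 4.64e-09).

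Platelet markers at VarDR day 5 rose in 17 of 18 (18 list alone, median 1.43, camera q = 9.20e-28, and 0.00637 estimated). These included the adhesion protein Thbs1 (2.64 ± 0.33, q = 1.56e-08) and Itgb3 (1.97 ± 0.26, q = 8.19e-08). Mature neutrophil markers rose in 10 of 15 (11 list alone, median 1.14, camera q = 4.98e-08, but 0.111 estimated). Examples were Csf3r (1.29 ± 0.24, q = 5.45e-05) and Clec4e (1.52 ± 0.30, q = 1.62e-04). Monocyte markers rose in 1 and fell in 3 of 15 (1 higher and 5 lower list alone, median −0.23, camera q = 0.0353, but 0.495 estimated). Members were F13a1 (1.05 ± 0.20, q = 1.23e-04) higher and Adgre4 (−0.77 ± 0.19, q = 0.00313) lower. Eosinophil and basophil markers fell in 4 of 11 (1 higher and 5 lower list alone, median −0.84, camera q = 4.61e-04, and 0.0255 estimated). Among them were Prg2 and Ccr3 (−1.47 ± 0.42, q = 0.0164). Interferon-stimulated genes rose in 1 and fell in 4 of 26 (1 higher and 4 lower list alone, median −0.26, camera q = 0.00183, but 0.359 estimated). These included Ifit2 (0.90 ± 0.18, q = 2.82e-04) higher and Irf7 (−1.12 ± 0.27, q = 0.00327) lower. Ribosomal protein genes fell in 9 of 54 (28 list alone, median −0.37, −0.59 after quantile, camera q = 1.09e-15, but 0.273 estimated). Examples were Rps15 (−0.49 ± 0.15, q = 0.0258) and Rpl11 (−0.55 ± 0.17, q = 0.0259). Cell cycle genes passed as a group without single members past the threshold (median −0.21, camera q = 0.0322, but 0.633 estimated). Camera passed 11 of the 22 lists, and the others had q 0.0528–0.944. Leaving out 1 library ended the calls of Ercc1, Ccr3, Rps15 and Rpl11, the ribosomal genes without irradiated replicate 6 (adjusted p = 0.266 and 0.303). With only the compared groups in the fit the count was 594 (452 higher, 142 lower).

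To find what remained at day 30, 6 mice given 9.7 Gy were compared with 6 shams. Of 21101 genes, 5301 passed an adjusted p of 0.05 (2670 higher, 2631 lower). 1513 higher and 1237 lower changed over 2-fold (median of all genes −0.18). Irradiated libraries had fewer genes above 0 (15637–19039) than shams (19842–23414), and the effect on calls was not tested. p53 targets rose in 11 and fell in 2 of 26 (12 higher and 2 lower list alone, median 0.46, camera q = 2.80e-04, and 0.00147 estimated): Cdkn1a (114 ± 52.7 against 29.9 ± 21.9 in shams, 2.00 ± 0.57, q = 0.00591), Phlda3 (2.09 ± 0.26, q = 1.57e-08), Ccng1 (0.75 ± 0.11, q = 7.95e-07), Mdm2 (0.49 ± 0.13, q = 0.0025), Bax (0.46 ± 0.13, q = 0.00486) and Eda2r (3.08 ± 0.76, q = 0.00134) rose, while Aen (−0.01 ± 0.22, q = 0.99) did not pass. Red cell markers rose in 23 of 24 (24 list alone, median 1.58, 0.64 after quantile, camera q = 2.71e-16, but 0.0972 estimated), opposite to their fall on day 3, with Rhag (2.06 ± 0.32, q = 1.40e-06) and Gata1 (1.42 ± 0.25, q = 9.69e-06). Gata1 also rose on VarDR day 5 (0.82, q = 0.0253), where the red cell score did not differ. Haemoglobin genes rose in 6 of 7 (6 list alone, median 1.68, 0.48 after quantile, camera q = 2.03e-04, but 0.126 estimated). Members were Hbb-y (2.70 ± 0.59, q = 2.68e-04) and Hba-a2 (1.66 ± 0.39, q = 7.22e-04), the latter uncertain for its near-identical copy. The haemoglobin share did not differ (4.51 ± 0.703 against 3.8 ± 1.33%, exact permutation p = 0.273). Cell cycle genes rose in 22 of 30 (24 list alone, median 1.37, camera q = 7.56e-15, but 0.0505 estimated). Among them were Cenpe (1.94 ± 0.28, q = 1.86e-07) and Kif11 (1.55 ± 0.23, q = 5.28e-07). B cell markers fell in 22 of 23 (23 list alone, median −1.20, camera q = 1.08e-17, but 0.0505 estimated). These included Ighd (−1.54 ± 0.21, q = 1.13e-07). MHC class II genes fell in 10 of 11 (11 list alone, mean −1.05, camera q = 9.84e-11, but 0.0582 estimated). Examples were H2-Ob (−1.40 ± 0.18, q = 4.16e-08) and Ciita (−1.43 ± 0.19, q = 8.01e-08). T cell markers fell in 10 of 23 (11 list alone, median −0.51, camera q = 1.20e-04, but not past 0.05 when estimated). Members were Ccr7 (−1.08 ± 0.20, q = 2.65e-05) and Cd8a (−1.23 ± 0.23, q = 2.84e-05).

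Platelet markers on day 30 rose in 14 of 18 (17 list alone, median 1.03, 0.40 after quantile, camera q = 1.37e-12, but 0.0972 estimated). Among them were P2ry12 (1.74 ± 0.21, q = 1.65e-08) and Gp9 (1.69 ± 0.26, q = 6.79e-07). Immature neutrophil granule genes rose in 3 of 9 (3 list alone, median 1.10, camera q = 0.021, but 0.389 estimated). These included Ngp (3.09 ± 0.77, q = 0.00148) and Camp (3.00 ± 0.98, q = 0.0168). Mature neutrophil markers rose in 1 of 15 (0 list alone, median 0.61, 0.33 after quantile, camera q = 0.00695, but not past 0.05 when estimated). The gene was the alarmin S100a9 (1.02 ± 0.39, q = 0.0466). Interferon-stimulated genes rose in 12 and fell in 1 of 26 (12 higher and 1 lower list alone, median 0.43, camera q = 1.64e-06, but 0.0972 estimated). Members were Herc6 (1.53 ± 0.24, q = 1.40e-06) and Irf7 (1.65 ± 0.27, q = 3.90e-06). NRF2 genes, the antioxidant set, rose in 9 of 13 (9 list alone, median 1.06, 0.46 after quantile, camera q = 9.88e-07, but 0.0505 estimated). Among them were Gclc (1.47 ± 0.26, q = 9.84e-06) and Srxn1 (1.30 ± 0.23, q = 1.63e-05). Ribosomal protein genes rose in 19 and fell in 1 of 54 (19 higher and 1 lower list alone, median 0.18, turning to −0.37 after quantile normalization, camera q = 9.88e-07, but not past 0.05 when estimated). These included Rplp0 (1.44 ± 0.20, q = 1.62e-07) and Rps29 (1.30 ± 0.19, q = 2.87e-07). Highest were Ugt8a (4.88 ± 0.79, q = 1.92e-06), AA465934 (4.24 ± 1.48, q = 0.027) and Nacad (3.47 ± 0.83, q = 8.69e-04), lowest Srms (−3.92 ± 0.67, q = 5.93e-06), LT629148.3 (−3.71 ± 1.00, q = 0.00328) and Olfr398 (−3.64 ± 0.77, q = 1.73e-04). Camera passed 13 of the 22 lists, and the others had q 0.0735–0.988. Leaving out 1 library ended the calls of AA465934 and S100a9, and quantile normalization those of Mdm2 (0.28), S100a9 (0.24), Hba-a2 (0.21), Rplp0 (0.15) and Rps29 (0.16).

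To find the response 2 days after 2 Gy given acutely, 6 irradiated mice were compared with 6 shams. Of 21101 genes, 3132 passed an adjusted p of 0.05 (1555 higher, 1577 lower, or 5930 with library weights). 863 higher and 942 lower changed over 2-fold (median of all genes 0.05). As deposited the split was 5426 higher and 876 lower, with a median of 0.50. p53 targets rose in 14 and fell in 1 of 26 (18 higher and 1 lower list alone, median 0.83, camera q = 3.60e-09, and 8.59e-08 estimated). Examples were Cdkn1a (198 ± 78.5 against 31.3 ± 27.2 in shams, 2.90 ± 0.57, q = 5.60e-05), Phlda3 (2.82 ± 0.26, q = 1.53e-14), Ccng1 (1.18 ± 0.11, q = 1.09e-13), Bax (1.09 ± 0.13, q = 1.07e-10), Aen (0.97 ± 0.22, q = 5.87e-04), Mdm2 (0.49 ± 0.13, q = 0.00331) and Eda2r (2.83 ± 0.76, q = 0.00416). Red cell markers rose in 1 and fell in 20 of 24 (2 higher and 21 lower list alone, median −3.71, camera q = 7.20e-38, and 0.00549 estimated). Members were Alas2 (33923 ± 9876 against 1046803 ± 618659 in shams, −4.85 ± 0.33, q = 6.06e-20) and the glycolytic mutase Bpgm (−5.61 ± 0.34, q = 1.25e-21) on chromosome 6 (34476207–34505613). Haemoglobin genes fell in 5 of 7 (5 list alone, median −4.38, camera q = 2.63e-11, and 0.00464 estimated). Among them were Hbb-bt (−5.63 ± 0.44, q = 1.19e-16) and Hba-a2 (−4.38 ± 0.39, q = 7.79e-15), whose copies share reads and are uncertain. The lowest gene was Aldh3b2 (−6.72 ± 0.42, q = 1.25e-21) on chromosome 19 (3972328–3981646), and the highest were Tnfsf4 (5.22 ± 0.68, q = 3.03e-09), Hjv (4.48 ± 1.24, q = 0.00555) and Saa1 (4.47 ± 1.19, q = 0.0036). Hjv and Saa1 are made in liver and gave 2.42 and 2.41 with liver covariates (limma adjusted p = 0.0499 and 0.0229), Saa1 did not pass with only the compared groups, and 3 of the 6 irradiated libraries but 1 of 6 shams had over 0.5% of their signal in 25 liver markers.

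B cell markers 2 days after the acute dose fell in 23 of 23 (23 list alone, median −2.07, camera q = 9.94e-50, and 1.83e-04 estimated). These included Ighd (−2.76 ± 0.21, q = 1.45e-17) and Fcer2a (−3.01 ± 0.25, q = 3.39e-16). Genes of MHC class II fell in 11 of 11 (11 list alone, mean −1.99, camera q = 3.19e-32, and 1.83e-04 estimated). Examples were H2-Ob (−2.36 ± 0.18, q = 1.33e-17) and H2-Ab1 (lower 3.99-fold, q = 1.84e-16). NK and cytotoxic markers rose in 15 of 15 (15 list alone, median 1.68, camera q = 4.12e-17, and 0.0256 estimated). Members were Il2rb (1.79 ± 0.25, q = 2.75e-08) and Tbx21 (1.83 ± 0.27, q = 9.04e-08). T cell markers rose in 10 and fell in 1 of 23 (13 higher and 2 lower list alone, median 0.54, camera q = 0.0025, but 0.542 estimated). Among them were Bcl11b (0.77 ± 0.19, q = 0.00147) higher and Ccr7 (−1.23 ± 0.20, q = 1.23e-06) lower. Platelet markers rose in 18 of 18 (18 list alone, median 2.03, camera q = 1.43e-29, and 0.00464 estimated). These included Tubb1 (2.30 ± 0.23, q = 7.20e-13) and Itgb3 (2.50 ± 0.26, q = 3.03e-12). Mature neutrophil markers rose in 8 of 15 (8 list alone, median 0.92, camera q = 2.79e-05, but 0.224 estimated). Examples were Mmp9 (1.27 ± 0.23, q = 1.46e-05) and Csf3r (1.17 ± 0.24, q = 8.52e-05).

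Monocyte markers on acute day 2 rose in 1 and fell in 8 of 15 (2 higher and 8 lower list alone, median −0.71, camera q = 0.0491, but 0.511 estimated). Members were F13a1 (1.58 ± 0.20, q = 2.03e-09) higher and Adgre4 (−1.12 ± 0.19, q = 1.57e-06) lower. DNA repair genes rose in 1 and fell in 3 of 31 (1 higher and 3 lower list alone, median −0.15, turning to 0.33 as deposited, camera q = 0.043, but 0.0928 estimated). Among them were Parp1 (−0.94 ± 0.11, q = 1.88e-10) and Fancd2 (−1.54 ± 0.32, q = 1.62e-04). Cell cycle genes fell in 5 of 30 (5 list alone, median −0.09, turning to 0.38 as deposited, camera q = 0.0412, but 0.588 estimated). These included Ube2c (−3.88 ± 0.37, q = 1.25e-13) and Nusap1 (−3.64 ± 0.37, q = 2.14e-12). Ribosomal protein genes fell in 32 of 54 (44 list alone, median −0.49, camera q = 9.49e-19, but 0.173 estimated). Examples were Rplp0 (−1.55 ± 0.20, q = 2.75e-09) and Rps29 (−1.25 ± 0.19, q = 1.56e-07). Camera passed 13 of the 22 lists, and the others had q 0.084–0.882.

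To find the response 3 days after 2.8 Gy given acutely, 3 irradiated mice were compared with 6 shams. Of 21101 genes, 4337 passed an adjusted p of 0.05 (2494 higher, 1843 lower, or 7996 with library weights). 1832 higher and 1188 lower changed over 2-fold (median of all genes 0.30). Genes above 0 numbered 24589–27535 (shams 16684–22783), with untested effect. As deposited the split was 11711 higher and 601 lower, with a median of 1.20 (0.08 after quantile normalization). p53 targets rose in 14 and fell in 2 of 26 (15 higher and 2 lower list alone, median 0.91, camera q = 2.75e-05, and 1.24e-04 estimated): Cdkn1a (302 ± 65.7 against 20.9 ± 9.48 in shams, 3.89 ± 0.70, q = 1.11e-05), Phlda3 (2.92 ± 0.32, q = 8.98e-12), Ccng1 (1.15 ± 0.14, q = 4.21e-10), Bax (1.01 ± 0.16, q = 4.26e-07), Eda2r (3.25 ± 0.94, q = 0.00772) and Aen (0.80 ± 0.27, q = 0.0279) rose, while Mdm2 (0.26 ± 0.16, q = 0.256) did not pass, although as deposited it gave 1.27 (limma adjusted p = 2.49e-10). Red cell markers rose in 1 and fell in 22 of 24 (1 higher and 22 lower list alone, median −4.94, camera q = 9.50e-47, and 0.00201 estimated). Members were Alas2 (5207 ± 1635 against 1326830 ± 274117 in shams, −8.01 ± 0.40, q = 3.82e-27), the lowest of all, and Bpgm (−7.86 ± 0.42, q = 3.43e-25). Haemoglobin genes fell in 4 of 7 (5 list alone, median −7.66, camera q = 1.42e-14, and 9.39e-04 estimated). Among them were Hbb-bs (−7.99 ± 0.50, q = 1.48e-21), Hbb-bt (−7.88 ± 0.54, q = 1.60e-19), Hba-a1 (−7.85 ± 0.49, q = 1.09e-21) and Hba-a2 (−7.66 ± 0.48, q = 6.06e-22), each uncertain because copies share reads. The highest were the liver products Fga (7.80 ± 2.29, q = 0.0096), Serpina1d (7.61 ± 2.27, q = 0.0109) and Serpina1c (7.54 ± 2.28, q = 0.0123), the last 2 near-identical copies and uncertain; all 3 lost their calls without irradiated replicate 1 or 2, and with liver covariates (0.95, 0.81 and 0.74). These 2 libraries had over 0.5% of signal in 25 liver markers, against 0 of 6 shams.

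B cell markers 3 days after the acute dose fell in 22 of 23 (23 list alone, median −2.39, camera q = 8.67e-49, and 3.22e-04 estimated). These included Ighd (−4.09 ± 0.26, q = 6.59e-22) and Fcer2a (−4.20 ± 0.31, q = 4.96e-19), the IgD chain on chromosome 12 (113406604–113416324) and the low-affinity IgE receptor on chromosome 8 (3681737–3694175). MHC class II genes fell in 11 of 11 (11 list alone, median −1.99, camera q = 1.24e-25, and 9.39e-04 estimated). Examples were H2-Ob (−2.98 ± 0.22, q = 1.17e-18) and H2-Oa (−2.95 ± 0.27, q = 1.64e-14). NK and cytotoxic markers rose in 13 of 15 (14 list alone, median 1.21, camera q = 1.45e-06, but 0.277 estimated). Members were Tbx21 (2.02 ± 0.33, q = 1.22e-06) and Il2rb (1.55 ± 0.31, q = 6.57e-05). Platelet markers rose in 18 of 18 (18 list alone, median 2.07, camera q = 1.06e-17, and 0.0347 estimated). Among them were Itgb3 (2.68 ± 0.32, q = 3.38e-10) and Thbs1 (3.23 ± 0.40, q = 1.16e-09). Cell cycle genes fell in 7 of 30 (7 list alone, median −0.27, turning to 0.74 as deposited, camera q = 4.10e-05, but 0.313 estimated). These included Ube2c (−5.42 ± 0.45, q = 5.77e-16) and Nusap1 (−4.73 ± 0.46, q = 2.48e-13).

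DNA repair genes on acute day 3 rose in 1 and fell in 7 of 31 (1 higher and 7 lower list alone, median −0.28, turning to 0.74 as deposited, camera q = 0.00123, and 0.00569 estimated). Examples were Parp1 (−1.10 ± 0.14, q = 7.47e-10) and Fancd2 (−1.98 ± 0.40, q = 7.10e-05), where Parp1 did not pass as deposited. Ribosomal protein genes fell in 48 of 54 (53 list alone, median −0.84, turning to 0.18 as deposited, camera q = 1.17e-32, and 0.0449 estimated). Members were Rpl41 (−2.85 ± 0.36, q = 1.66e-09) and Rplp0 (−1.92 ± 0.25, q = 2.39e-09). Camera passed 10 of the 22 lists, and the others had q 0.132–0.957. Without irradiated replicate 1 the count was 2625 (1269 higher, 1356 lower), without replicate 2 it was 2762 (1366 higher, 1396 lower), and without the 2 liver-heavy irradiated libraries 1644 (724 higher, 920 lower), where 1 irradiated library is left and a liver effect cannot be read from the drop. The calls of Aen and Eda2r also ended when 1 library was left out.

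To find the response 5 days after 4.1 Gy given acutely, 6 irradiated mice were compared with 6 shams. Of 21101 genes, 3983 passed an adjusted p of 0.05 (2059 higher, 1924 lower, or 6508 with library weights). 1129 higher and 983 lower changed over 2-fold (median of all genes 0.02). As deposited the split was 10125 higher and 442 lower, with a median of 0.88. p53 targets rose in 13 and fell in 2 of 26 (15 higher and 2 lower list alone, median 0.61, camera q = 1.11e-05, and 1.83e-05 estimated): Cdkn1a (172 ± 60.1 against 28.2 ± 18.1 in shams, 2.99 ± 0.57, q = 3.12e-05), Phlda3 (2.89 ± 0.26, q = 4.34e-15), Ccng1 (1.20 ± 0.11, q = 4.23e-14), Bax (0.67 ± 0.13, q = 2.51e-05), Eda2r (3.65 ± 0.76, q = 1.39e-04) and Aen (0.60 ± 0.22, q = 0.0476) rose, while Mdm2 (0.27 ± 0.13, q = 0.16) did not pass, although as deposited it gave 1.22 (limma adjusted p = 7.22e-13). B cell markers fell in 23 of 23 (23 list alone, median −3.65, camera q = 6.89e-87, and 1.89e-06 estimated), the largest fall of this list, with Ighd (113 ± 28.3 against 4391 ± 385 in shams, −5.30 ± 0.21, q = 2.25e-33) and Fcer2a (−5.66 ± 0.25, q = 7.52e-31). Genes of MHC class II fell in 10 of 11 (10 list alone, median −1.46, camera q = 2.10e-25, and 0.00108 estimated). Among them were H2-Ob (−3.99 ± 0.18, q = 2.22e-30) and H2-DMb2 (−3.42 ± 0.18, q = 9.79e-27). Highest were the glutathione transferase Gstt1 (6.63 ± 0.98, q = 1.48e-07), Hjv (6.02 ± 1.24, q = 1.11e-04) and Olr1 (5.81 ± 0.63, q = 8.95e-12), and the lowest was Crisp3 (−5.75 ± 0.53, q = 9.99e-15), ahead of Fcer2a and Ighd. Liver markers held over 0.5% of the signal in 3 of the 6 irradiated libraries and 0 of 6 shams.

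Platelet markers 5 days after the acute dose rose in 18 of 18 (18 list alone, median 2.22, camera q = 1.45e-35, and 0.00183 estimated). These included Thbs1 (3.99 ± 0.33, q = 2.30e-16) and Itgb3 (3.15 ± 0.26, q = 2.85e-16). Red cell markers rose in 2 and fell in 7 of 24 (2 higher and 9 lower list alone, median −0.72, turning to 0.23 as deposited, camera q = 0.00958, but 0.692 estimated). Examples were Alas2 (−1.73 ± 0.33, q = 2.46e-05) lower and Gata1 (1.29 ± 0.25, q = 4.03e-05) higher. Monocyte markers rose in 3 of 15 (3 list alone, median 0.32, camera q = 0.0154, but 0.431 estimated). Members were F13a1 (2.21 ± 0.20, q = 1.22e-14) and Ccr2 (1.55 ± 0.23, q = 7.16e-08). Eosinophil and basophil markers rose in 1 and fell in 5 of 11 (1 higher and 5 lower list alone, median −1.17, camera q = 0.0034, but 0.065 estimated). Among them were Il5ra (−2.17 ± 0.31, q = 4.10e-08) and Ms4a2 (−2.97 ± 0.45, q = 2.01e-07). NK and cytotoxic markers rose in 8 of 15 (11 list alone, median 0.78, camera q = 4.85e-05, but 0.431 estimated). These included Il2rb (1.41 ± 0.25, q = 8.39e-06) and Tbx21 (1.32 ± 0.27, q = 8.87e-05).

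Mature neutrophil markers on acute day 5 rose in 7 of 15 (9 list alone, median 0.78, camera q = 0.0024, but 0.431 estimated). Examples were Mmp8 (1.74 ± 0.37, q = 1.94e-04) and Mmp9 (0.92 ± 0.23, q = 0.00204). DNA repair genes rose in 1 and fell in 9 of 31 (1 higher and 9 lower list alone, median −0.15, turning to 0.79 as deposited, camera q = 0.00958, and 0.0358 estimated). Members were Parp1 (−1.13 ± 0.11, q = 1.79e-13) and Fanci (−1.29 ± 0.26, q = 6.96e-05), which did not pass as deposited. Ribosomal protein genes fell in 53 of 54 (53 list alone, median −0.78, turning to 0.18 as deposited, camera q = 3.08e-31, but 0.065 estimated). Among them were Rps7 (−1.13 ± 0.17, q = 7.95e-08) and Rps14 (−1.10 ± 0.16, q = 8.76e-08), which did not pass as deposited either. Camera passed 11 of the 22 lists, and the others had q 0.0525–0.931. The call of Aen ended without any of 10 of the 12 libraries.

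**Figure D1:**
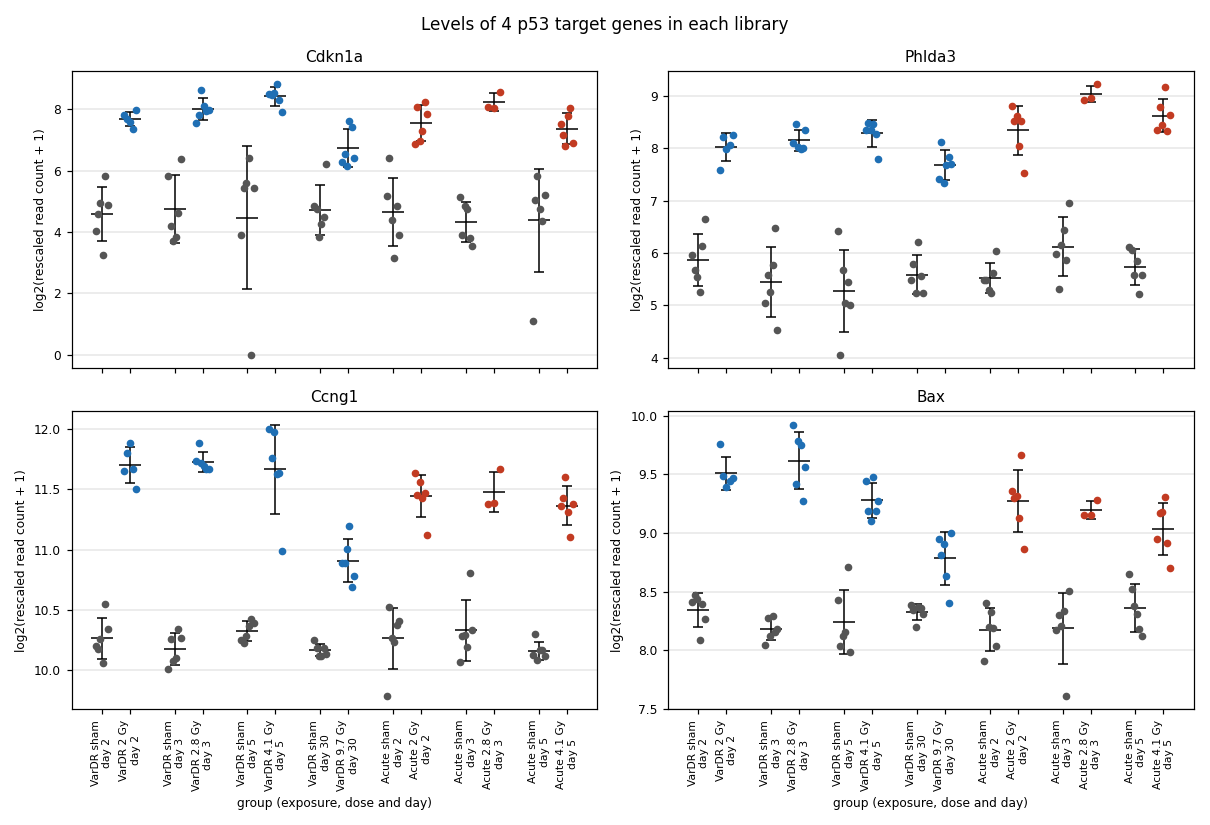
Log2 rescaled read count + 1 of Cdkn1a, Phlda3, Ccng1 and Bax in each library of the 14 groups, with group mean ± SD. Grey is sham, blue VarDR and red acute.

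**Figure D2:**
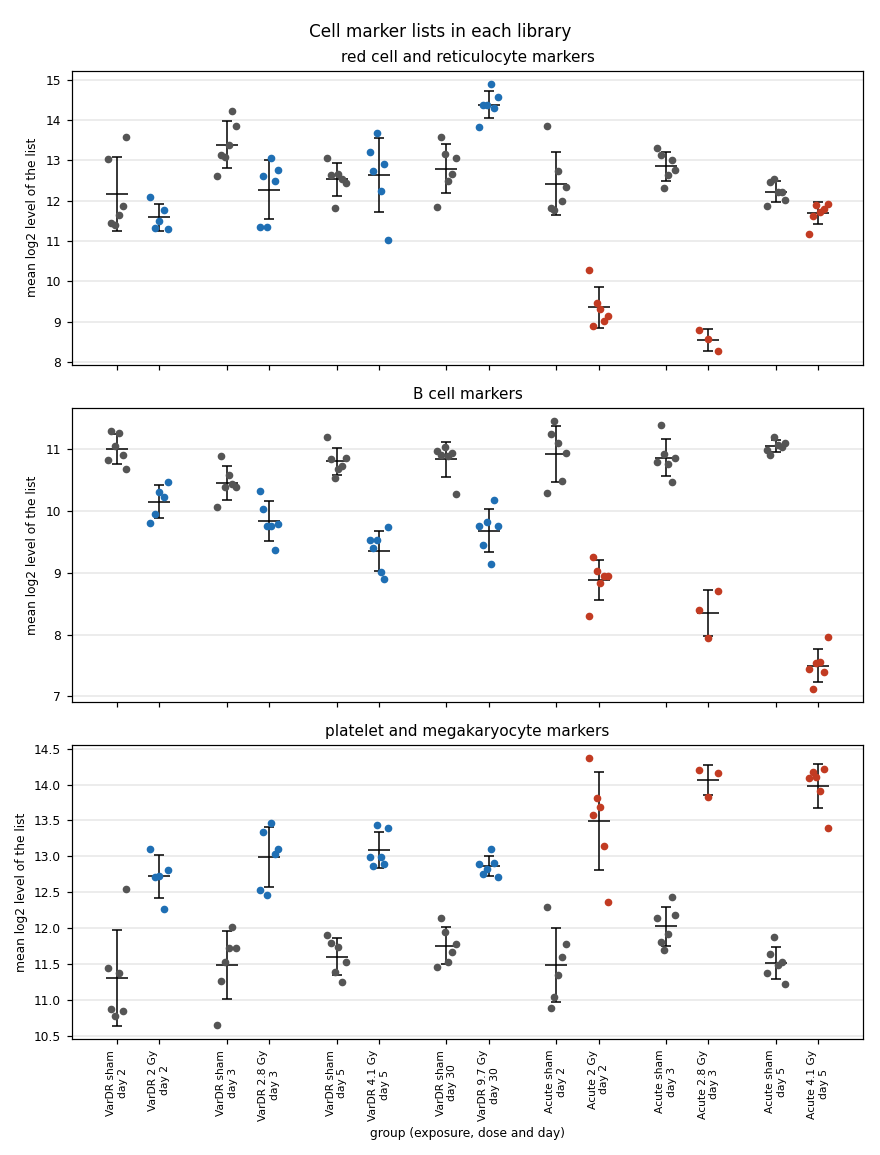
Mean log2 level of red cell, B cell and platelet markers in each library, with group mean ± SD. The red cell median of acute day 5 (−0.72) turned to 0.23 as deposited.

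To compare the 2 exposures at equal dose, the VarDR response was subtracted from the acute response of the same day, each against its own shams. At day 2, 335 genes differed (41 higher, 294 lower after the acute dose, or 1437 with library weights), against 2213 higher and 225 lower as deposited and 116 higher and 369 lower after quantile normalization; the median of all genes was 0.08, and 0.54 as deposited. Lower were Aldh3b2 (−5.71 ± 0.61, q = 5.40e-10), Bpgm (−4.65 ± 0.50, q = 5.40e-10) and Hbb-bt (−4.45 ± 0.64, q = 1.47e-06), and higher Amer3 (2.85 ± 0.74, q = 0.0217), Slc6a3 (2.44 ± 0.60, q = 0.0127) and Bsn (2.34 ± 0.65, q = 0.0403). The p53 targets Cdkn1a (−0.20 ± 0.83, q = 0.973), Phlda3 (0.67 ± 0.37, q = 0.612), Ccng1 (−0.26 ± 0.17, q = 0.692), Mdm2 (−0.02 ± 0.19, q = 0.99), Bax (−0.07 ± 0.19, q = 0.955), Aen (−0.15 ± 0.33, q = 0.939) and Eda2r (1.82 ± 1.11, q = 0.66) did not pass, although as deposited Phlda3 gave 1.14 (limma adjusted p = 0.0351). With only the compared groups the count was 208. Leaving out 1 library ended the calls of Amer3, Slc6a3 and Bsn.

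Fixed lists differed on day 2, but any separate handling of acute groups cannot be told apart from exposure. Both group tests passed for B cell markers (median −1.17, 6.61e-34, 0.00266 estimated), MHC class II genes (median −1.13, 3.90e-21, 0.00266 estimated), red cell markers (median −2.78, 6.78e-48, 0.00266 estimated) and haemoglobin genes (median −3.47, 6.77e-13, 0.00266 estimated), with camera q for the preset and then the estimated correlation. Only with the preset correlation did camera pass NK and cytotoxic markers (median 0.82, 2.77e-07, 0.335 estimated), eosinophil and basophil markers (median −0.63, 0.0379, 0.331 estimated), platelet markers (median 0.52, 4.78e-05, 0.516 estimated) and ribosomal protein genes (median −0.21, turning to 0.27 as deposited, 2.77e-07, 0.55 estimated).

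At day 3, 530 genes differed (139 higher, 391 lower after the acute dose, or 2635 with library weights), against 8948 higher and 189 lower as deposited, with a median of 0.23 that was 1.15 as deposited and 0.00 after quantile normalization. Lower were Hba-a1 (−6.85 ± 0.64, q = 6.26e-13), Hbb-bs (−6.71 ± 0.65, q = 2.70e-12) and Hba-a2 (−6.57 ± 0.62, q = 6.26e-13), uncertain as copies share reads, and higher the liver-expressed Ugt1a9 (9.47 ± 2.66, q = 0.0329), Hgd (8.26 ± 2.44, q = 0.0489) and Me1 (7.52 ± 2.22, q = 0.0477). The p53 targets Cdkn1a (0.65 ± 0.91, q = 0.771), Phlda3 (0.20 ± 0.41, q = 0.852), Ccng1 (−0.40 ± 0.18, q = 0.219), Mdm2 (−0.31 ± 0.20, q = 0.452), Bax (−0.43 ± 0.20, q = 0.246), Aen (−0.61 ± 0.35, q = 0.375) and Eda2r (−0.02 ± 1.21, q = 0.996) did not pass, but as deposited Ccng1, Mdm2 and Bax turned to 0.60, 0.69 and 0.57 and Phlda3 gave 1.20 (limma adjusted p = 0.0143). The count was 320 (41 higher, 279 lower) without acute replicate 1 and 352 (68 higher, 284 lower) without replicate 2, and leaving out 1 library ended the calls of Ugt1a9, Hgd and Me1, as did liver covariates (2.68, 1.67 and 2.50). Without libraries over 0.5% liver markers it was 139 (5 higher, 134 lower), with 1 acute irradiated library left, and without a filter 865.

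Lists also differed on day 3. Both group tests passed for B cell markers (median −1.73, 2.14e-51, 4.17e-04 estimated), MHC class II genes (median −1.30, 1.56e-22, 0.00185 estimated), plasma cell markers (median −0.83, turning to 0.17 as deposited, 1.54e-04, 0.0142 estimated), red cell markers (median −3.51, 4.50e-49, 0.00185 estimated) and haemoglobin genes (median −6.44, 5.39e-17, 5.56e-04 estimated). Only with the preset correlation did camera pass p53 targets (median −0.17, turning to 0.78 as deposited, mean 0.21, 0.0447, 0.0576 estimated), DNA repair genes (median −0.11, turning to 0.88 as deposited, 0.0477, 0.109 estimated), T cell markers (median −0.42, turning to 0.58 as deposited, 4.31e-07, 0.247 estimated) and NK and cytotoxic markers (median 0.55, 0.0217, 0.616 estimated). The preset correlation alone also passed mature neutrophil markers (median −0.94, turning to 0.06 as deposited, 2.06e-06, 0.129 estimated), monocyte markers (median 0.40, 0.0394, 0.467 estimated), eosinophil and basophil markers (median −0.68, 0.0359, 0.168 estimated) and platelet markers (median 0.48, 0.038, 0.684 estimated). So it was for NF-kB genes (median −0.19, turning to 0.78 as deposited, 0.00248, 0.109 estimated), ribosomal protein genes (median −0.54, turning to 0.47 as deposited, 5.69e-22, 0.109 estimated) and lung cell markers (median −1.11, 0.00317, 0.0504 estimated).

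At day 5, 561 genes differed (213 higher, 348 lower after the acute dose, or 1261 with library weights), against 7512 higher and 164 lower as deposited and 157 higher and 411 lower after quantile normalization, with a median of −0.04 that was 0.84 as deposited. Higher were Gstt1 (5.42 ± 1.39, q = 0.0173), Zbbx (4.22 ± 0.60, q = 7.81e-07) and Misp (4.19 ± 1.21, q = 0.039), lower Ptgs2 (−4.58 ± 1.13, q = 0.0112), Trpm5 (−4.41 ± 1.21, q = 0.0272) and Stag3 (−4.19 ± 1.16, q = 0.0299); Ptgs2 makes prostaglandins. The p53 targets Cdkn1a (−0.97 ± 0.81, q = 0.623), Phlda3 (−0.12 ± 0.37, q = 0.913), Ccng1 (−0.14 ± 0.16, q = 0.748), Mdm2 (−0.50 ± 0.18, q = 0.133), Bax (−0.36 ± 0.18, q = 0.311), Aen (−0.31 ± 0.32, q = 0.71) and Eda2r (−1.31 ± 1.08, q = 0.615) did not pass, but as deposited Ccng1, Mdm2 and Bax turned to 0.82, 0.46 and 0.60. The count was 314 with only the compared groups and 882 with liver covariates. The calls of Misp, Trpm5 and Stag3 ended when 1 library was left out.

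On day 5 both group tests passed for B cell markers alone (median −1.97, 9.22e-66, 4.21e-05 estimated). Only with the preset correlation did camera pass p53 targets (median −0.31, turning to 0.64 as deposited, 0.0335, 0.104 estimated), MHC class II genes (median −0.06, turning to 0.90 as deposited, 4.04e-05, 0.353 estimated), NK and cytotoxic markers (median 0.39, 0.00377, 0.668 estimated) and monocyte markers (median 0.71, 7.58e-07, 0.118 estimated). The preset correlation alone also passed red cell markers (median −0.75, turning to 0.21 as deposited, 0.00312, 0.668 estimated), platelet markers (median 0.95, 1.41e-11, 0.214 estimated), interferon-stimulated genes (median 0.24, 0.00938, 0.584 estimated) and NF-kB genes (median −0.43, turning to 0.52 as deposited, 0.00631, 0.279 estimated). So it was for cell cycle genes (median 0.23, 0.0321, 0.668 estimated) and ribosomal protein genes (median −0.42, turning to 0.54 as deposited, 9.08e-12, 0.468 estimated).

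To find how many genes both exposures moved in the same direction, the calls of each day were intersected. On day 2, 498 genes rose and 119 fell after both, against 39.3 and 11.7 expected of independent lists; on day 3, 723 rose and 826 fell (128 and 96.5 expected); on day 5, 720 rose and 435 fell (111 and 65 expected). Opposite calls numbered 0, 5 and 17. Cdkn1a, Phlda3, Ccng1, Bax and Aen rose after both on all 3 days.

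To compare the VarDR responses of day 2 (2 Gy) and day 5 (4.1 Gy), in which day, dose and dose rate change together, the 2 differences from sham were subtracted. The gene Gm10145 alone differed (−4.88 ± 0.93, limma adjusted p = 0.0283; 1716 genes at an unadjusted p under 0.05), and it was chosen after its values were seen. The median of all genes was 0.10, as deposited 2 rose and 2 fell, and other choices gave counts of 0 to 10. Leaving out 1 of 20 of the 23 libraries moved the count, at most to 22 without VarDR day 5 replicate 6. Only with the preset correlation did camera pass DNA repair genes (median −0.23, 0.0483, 0.193 estimated), B cell markers (median −0.60, 1.09e-13, 0.193 estimated), MHC class II genes (median −0.48, 2.12e-06, 0.285 estimated) and T cell markers (median −0.21, 0.0106, 0.749 estimated). The preset correlation alone also passed NK and cytotoxic markers (median −0.48, 1.90e-04, 0.678 estimated), eosinophil and basophil markers (median −0.89, 1.89e-04, 0.0648 estimated), red cell markers (median 0.80, 0.30 after quantile, 4.19e-04, 0.749 estimated) and heart muscle markers (median 2.34, 0.00164, 0.341 estimated).

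Between VarDR day 5 (4.1 Gy) and day 30 (9.7 Gy), where the same confounding holds, the responses of 2643 genes differed (1414 higher, 1229 lower), with a median of −0.25. The count was 1718 (1047 higher, 671 lower) without VarDR day 5 replicate 6, 1759 (837 higher, 922 lower) after quantile normalization, 1660 with library weights and 1159 (863 higher, 296 lower) with only the compared groups. Both group tests passed for p53 targets (median −0.57, 0.00655, 0.0309 estimated) and, higher at day 30, interferon-stimulated genes (median 0.93, 1.00e-10, 0.0343 estimated) and cell cycle genes (median 1.43, 2.68e-18, 0.0309 estimated). Only with the preset correlation did camera pass DNA repair genes (median 0.22, 0.0261, 0.147 estimated), B cell markers (median 0.29, 0.13 after quantile, 0.00614, 0.487 estimated), MHC class II genes (median 0.39, 0.12 after quantile, 0.0153, 0.479 estimated) and T cell markers (median −0.62, 3.52e-05, 0.371 estimated). The preset correlation alone also passed immature neutrophil granule genes (median 1.72, 0.00488, 0.208 estimated), monocyte markers (median 0.42, 0.00488, 0.286 estimated), eosinophil and basophil markers (median 0.62, 0.0153, 0.167 estimated) and red cell markers (median 1.64, 0.68 after quantile, 5.87e-14, 0.167 estimated). So it was for haemoglobin genes (median 1.64, 0.52 after quantile, 9.36e-04, 0.167 estimated), NRF2 genes (median 0.53, 0.33 after quantile, 0.00264, 0.167 estimated), ribosomal protein genes (median 0.59, 0.18 after quantile, 5.72e-23, 0.167 estimated) and heart muscle markers (median −3.08, 0.00488, 0.245 estimated). Heart markers lay near 0 in most libraries (Myh6 on day 30 was 0 against 392 ± 944 in shams), so both their medians may rest on few.

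Between acute days 2 (2 Gy) and 5 (4.1 Gy), where day and dose change together, the responses of 349 genes differed (288 higher, 61 lower), against 1997 higher and 35 lower as deposited, with a median of −0.04 (0.39 as deposited). Library weights gave 672 and liver covariates 552. The fall of red cell markers was smaller and that of B cell markers larger at 4.1 Gy and day 5. Both group tests passed for B cell markers (median −1.45, 1.11e-60, 9.31e-05 estimated), monocyte markers (median 0.98, 2.54e-11, 0.0101 estimated), red cell markers (median 2.69, 1.54e-54, 0.00122 estimated) and haemoglobin genes (median 2.85, 5.16e-16, 8.00e-04 estimated). Only with the preset correlation did camera pass T cell markers (median −0.37, turning to 0.11 as deposited, 6.55e-05, 0.449 estimated), NK and cytotoxic markers (median −0.80, 1.00e-08, 0.2 estimated), eosinophil and basophil markers (median −0.38, turning to 0.08 as deposited, 0.0449, 0.253 estimated) and platelet markers (median 0.56, turning to −0.07 after quantile normalization, 2.09e-04, 0.449 estimated). The preset correlation alone also passed NF-kB genes (median −0.31, turning to 0.16 as deposited, 0.0119, 0.253 estimated), cell cycle genes (median 0.23, 3.19e-04, 0.428 estimated), NRF2 genes (median 0.55, 2.46e-05, 0.0612 estimated) and ribosomal protein genes (median −0.26, turning to 0.21 as deposited, 1.83e-06, 0.453 estimated).

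To learn how far shams of the 2 exposures differed, acute shams were compared with VarDR shams of the same day. On day 2, 0 genes passed (limma, 513 at an unadjusted p under 0.05). On day 3, AI839979 (−2.83 ± 0.47, adjusted p = 0.00152) and Rilp (−3.51 ± 0.63, adjusted p = 0.0039) passed limma, and they were chosen after their values were seen. At an unadjusted p under 0.05 there were 3224 genes. The count was 86 without acute sham replicate 1, 30 without VarDR sham replicate 2, 29 without acute sham replicate 4, 5 without acute sham replicate 5, 4 without VarDR sham replicate 1 and 1 without acute sham replicate 3 or 6. On day 5, 9 genes were higher in acute shams, with Zfp36l2 (0.72) among them, against 145 higher and 4350 lower as deposited and 103 higher and 16 lower after quantile normalization. Their count was 233 without VarDR sham replicate 1, 53 without VarDR sham replicate 3, 5 without acute sham replicate 2 or 4 and 3 without acute sham replicate 6. As deposited the medians of all genes were −0.25, −0.42 and −0.37, and after quantile normalization 0.04 on day 3 and 0.18 on day 5.

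**Figure D3:**
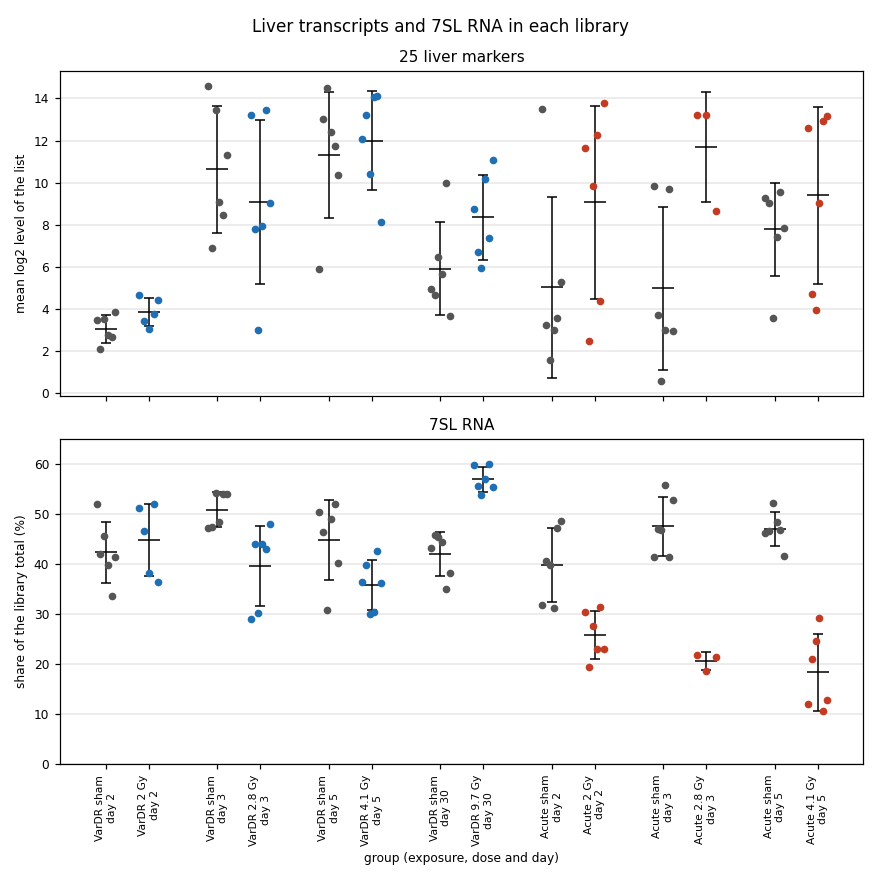
Mean log2 level of 25 liver markers and percent of signal in 7SL RNA for each library, with group mean ± SD.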

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

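The differences of responses, camera and the splits of the samples were set before the results were seen, and the tests weighing liver, red cell and 7SL transcripts were chosen after. In the outlier search 6 of 104 groups had a library apart, and chance alone gives about 1 in 20. They were the mt-Rnr2 share of acute day 5 replicate 5 (16.6%, others 1.4 to 5.55%), haemoglobin share of acute day 2 replicate 5 (1.21%, others 0.229 to 0.503%), liver score of acute sham day 2 replicate 1 (13.49, others 1.57 to 5.25) and acute sham day 5 replicate 3 (3.56, others 7.39 to 9.56), B cell score of VarDR sham day 30 replicate 6 (10.27, others 10.88 to 11.04) and platelet score of acute day 5 replicate 6 (13.40, others 13.91 to 14.21).

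Responses differed between exposures or days in 335, 530 and 561 genes for acute minus VarDR on days 2, 3 and 5, in 1 gene for VarDR day 5 minus day 2, in 2643 for VarDR day 30 minus day 5 and in 349 for acute day 5 minus day 2. Day 2 gave Amer3 2.85, Slc6a3 2.44, Bsn 2.34, Aldh3b2 −5.71, Bpgm −4.65 and Hbb-bt −4.45. Day 3 gave Ugt1a9 9.47, Hgd 8.26, Me1 7.52, Hba-a1 −6.85, Hbb-bs −6.71 and Hba-a2 −6.57. Day 5 gave Gstt1 5.42, Zbbx 4.22, Misp 4.19, Ptgs2 −4.58, Trpm5 −4.41 and Stag3 −4.19. Chance was tested by relabelling the samples in 100 splits, of which the real one is 1. The real count was matched or passed by 1 split for days 2 and 5 of acute minus VarDR (highest other split 215 and 332), by 2 for day 3 (624), by 1 for VarDR day 30 minus day 5 (2501) and by 1 for acute day 5 minus day 2 (27), so chance can be excluded at 1 or 2 in 100. For VarDR day 5 minus day 2, 29 of 100 splits matched the 1 gene and the highest called 1146, so chance cannot be excluded; what made that split call so many was not tested.

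Liver transcripts differed between libraries. RNA of liver cells in the samples is in line with 25 of 25 liver markers rising and falling together in 42 shams (Spearman rho over 0.8). Irradiation as their only source does not hold, as 6 of 42 shams had over 0.5% of signal in these markers. With liver covariates 2829 of 3132, 2945 of 4337 and 3562 of 3983 acute calls held on days 2, 3 and 5. Liver is not their whole cause.

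Red cell transcripts were lower on days 2 and 3 after acute exposure. Globin removal does not account for it, as red cell markers that are not haemoglobin genes had medians of −3.71 on day 2 and −4.94 on day 3. Scaling does not either, as the medians as deposited were −3.24 and −3.94. On day 5 the median of −0.72 turned to 0.23 as deposited, so scaling is not excluded there. A stronger loss of red cell RNA than after VarDR is consistent with camera on the difference of responses (adjusted p = 0.00266 and 0.00185 with an estimated correlation).

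The 7SL share fell after acute exposure (exact permutation p = 0.00433, 0.0119 and 0.00216 on days 2, 3 and 5). There, as in every acute result, irradiation cannot be told apart from any unstated separate handling of those libraries. It also differed from sham on VarDR days 3 and 30 (exact permutation p = 0.00649 and 0.00216), which says nothing about handling of the acute libraries. On acute day 5 the share minus its prediction from the red cell score in shams was −24.2 points. That score was 11.69 against 12.22 (slope 2.44 points per log2), so red cell loss could predict little of this. Days 2 and 3 were not tested.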

How the results depend on the processing

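All tests here apart from the alternatives fixed beforehand were chosen after the data or results were seen. Differences are acute minus VarDR responses. No paired analysis was possible because sample titles carry unique numbers and no shared replicate number. Library weights gave 2058 for VarDR day 2, 1103 for VarDR day 5, 5930 for acute day 2, 7996 for acute day 3, 6508 for acute day 5, 1437 for difference day 2, 2635 for difference day 3, 1261 for difference day 5, 5 for VarDR day 5 minus day 2, 1660 for VarDR day 30 minus day 5, 672 for acute day 5 minus day 2, 57 for shams day 2, 0 for shams day 3 and 2 for shams day 5. With only the compared groups in the fit, the counts were 594 for VarDR day 5, 208 for difference day 2, 314 for difference day 5, 0 for VarDR day 5 minus day 2, 1159 for VarDR day 30 minus day 5 and 0 for shams day 3. Values as deposited gave 6302 for acute day 2, 12312 for acute day 3, 10567 for acute day 5, 2438 for difference day 2, 9137 for difference day 3, 7676 for difference day 5, 4 for VarDR day 5 minus day 2, 2032 for acute day 5 minus day 2, 597 for shams day 2, 3335 for shams day 3 and 4495 for shams day 5. Without libraries over 0.5% liver markers the counts were 1644 for acute day 3, 139 for difference day 3, 10 for VarDR day 5 minus day 2, 4 for shams day 2 and 25 for shams day 5. Without a filter they were 865 for difference day 3, 1 for shams day 2 and 28 for shams day 5. Liver covariates gave 882 for difference day 5, 9 for VarDR day 5 minus day 2, 552 for acute day 5 minus day 2 and 4 for shams day 5. Quantile normalization gave 3 for VarDR day 5 minus day 2, 1759 for VarDR day 30 minus day 5, 1 for shams day 3 and 119 for shams day 5. A pseudocount of 0.1 gave 0 for VarDR day 5 minus day 2 and 28 for shams day 5. With an estimated correlation, the lists past camera numbered 4 for VarDR day 2, 3 for VarDR day 3, 6 for VarDR day 5, 1 for VarDR day 30, 7 for acute day 2, 5 for acute day 5, 4 for difference day 2, 5 for difference day 3, 1 for difference day 5, 0 for VarDR day 5 minus day 2, 3 for VarDR day 30 minus day 5 and 4 for acute day 5 minus day 2. With fry they numbered 6 for VarDR day 2, 4 for difference day 2, 7 for difference day 3, 6 for difference day 5, 0 for VarDR day 5 minus day 2 and 5 for acute day 5 minus day 2. Leaving out 1 library at a time gave gene counts of 452–740 for VarDR day 2, 1712–2209 for VarDR day 3, 1400–2218 for VarDR day 5, 4321–5416 for VarDR day 30, 2798–3438 for acute day 2, 2625–4620 for acute day 3, 3511–3758 for acute day 5, 274–426 for difference day 2, 320–710 for difference day 3, 394–726 for difference day 5, 0–22 for VarDR day 5 minus day 2, 1718–3135 for VarDR day 30 minus day 5, 260–375 for acute day 5 minus day 2, 0–0 for shams day 2, 1–86 for shams day 3 and 3–233 for shams day 5. Leaving out liver-heavy libraries leaves 1 irradiated library for acute day 3, so its counts show no liver effect. As deposited, acute irradiated libraries sit above their shams (by 0.950 log2 on day 5). Acute shams sit below VarDR shams, with day 5 medians of ratios over all libraries of 0.762 to 0.783 against 1.011 to 1.085. The cause of these offsets and of the other moves was not tested.

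As deposited, Ccng1 in acute minus VarDR turned to 0.60 on day 3 (limma adjusted p = 0.0067) and 0.82 on day 5 (3.58e-05), Mdm2 to 0.69 (0.00493) and 0.46 (0.0395), and Bax to 0.57 (0.0188) and 0.60 (0.00604). Of the 264 selected gene results, 246 stayed the same as deposited, 247 with quantile normalization, 254 with a pseudocount of 0.1, 254 without a filter, 257 with a mean value of at least 1, 252 with liver covariates and 235 with only the compared groups. Of the 455 passing calls of the whole rule set of 605 results, quantile normalization ended 30, a pseudocount of 0.1 ended 19, no filter 30, a mean value of at least 1 ended 10, values as deposited 36, liver covariates 29, and only the compared groups 71, and leaving out any 1 library ended 83. Among selected calls, 33 of 239 ended on leaving out 1 library.

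Calls lost with pseudocount 0.1 were Chrne and Exosc6 (VarDR day 2), AA465934, Sftpa1 and Sftpb (VarDR day 3), Ercc1 (VarDR day 5), Camp (VarDR day 30), Amer3 (difference day 2), Gstt1 and Misp (difference day 5). Lost at equal folds with only the compared groups were Rag1, Exosc6, Mdm2 and F13a1 (VarDR day 2), AA465934, Hbb-bs, Il1b, Sftpa1 and Sftpb (VarDR day 3), Prg2, Rag1, Aen, Ercc1, Ccr3, Rps15 and Rpl11 (VarDR day 5), Saa1 (acute day 2), Fga, Serpina1d, Serpina1c and Aen (acute day 3), Amer3, Slc6a3 and Bsn (difference day 2), Ugt1a9, Hgd and Me1 (difference day 3), Misp and Stag3 (difference day 5). Lost with quantile normalization were Cd74 (VarDR day 2), AA465934, H2-Aa, H2-Ab1, Alas2, Hbb-bt and Hbb-bs (VarDR day 3), Ercc1 (VarDR day 5), Mdm2, S100a9, Hba-a2, Rplp0 and Rps29 (VarDR day 30), Aen (acute days 3 and 5), Bsn (difference day 2), Stag3 (difference day 5). Lost at equal folds with no filter were Mrgpra2a, AA465934, Cd4, Hbb-bs and Sftpb (VarDR day 3), Ercc1 (VarDR day 5), S100a9 (VarDR day 30), Aen (acute day 5), Bsn (difference day 2), Misp (difference day 5). With mean value of at least 1 they were AA465934 and Sftpb (VarDR day 3), Ercc1 (VarDR day 5), S100a9 (VarDR day 30), Aen (acute day 5), Hgd and Me1 (difference day 3). Lost with liver covariates were AA465934, Cd4 and Sftpb (VarDR day 3), Ercc1 (VarDR day 5), AA465934 (VarDR day 30), Fga, Serpina1d, Serpina1c and Eda2r (acute day 3), Ugt1a9, Hgd and Me1 (difference day 3). Lost as deposited were Sftpa1 and Sftpb (VarDR day 3), S100a9 (VarDR day 30), Parp1 (acute day 3), Parp1, Fanci, Rps7 and Rps14 (acute day 5). The cause was not tested.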

Other observations

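Liver transcripts in blood varied widely between libraries. The 25 markers held 3.91% of the signal in 1 acute day 2 library, 4.35% in 1 VarDR sham of day 5 and as little as 1.39e-04% in 1 acute sham of day 3. No VarDR day 2 library had more than 0.00549%, while 4 of 6 VarDR day 5 libraries and 3 of 6 of their shams had over 0.5%. Kidney and skeletal muscle markers stayed low, with highest mean log2 levels of 2.04 and 3.60 in any library, as did skin markers (median 0.92), against 14.61 for liver, 4.03 for lung and 6.94 for heart markers.

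Tests here were chosen after the results were seen, apart from the cell cycle test and the splits. Some cell cycle transcripts in blood may come with young red cells: in 42 shams, centred by group, cell cycle and red cell scores had Pearson r = 0.85 and Spearman rho = 0.86 (permutation p = 1e-05, the smallest that 100000 resamples can give), r = 0.82 without the 2 farthest libraries, and a positive relation in all 7 groups. Platelet scores followed too (r = 0.76, rho = 0.74, permutation p = 1e-05, r = 0.69 without the 2 farthest), while B cell (r = −0.14, rho = −0.18, permutation p = 0.392, r = −0.06 without the 2 farthest) and neutrophil scores (r = −0.06, rho = −0.17, permutation p = 0.757, r = −0.22) did not. Against the list as a whole following red cells, the cell cycle median was −0.09 on acute day 2 and −0.27 on day 3, where red cell medians were −3.71 and −4.94, and 0.23 against 2.69 between acute days 2 and 5. Reticulocyte counts by flow cytometry beside the same RNA would test this.

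In comparisons with sham, only the real split of 100 (84 for acute day 3) reached the real count: 690 genes against at most 579 in another split for VarDR day 2, 2186 against 654 for day 3, 1854 against 1391 for day 5, 5301 against 3130 for day 30, and 3132 against 2707, 4337 against 1845 and 3983 against 1941 for acute days 2, 3 and 5, so chance can be excluded at 1 in 100 or 1 in 84. For shams, 100, 21 and 4 of 100 splits reached the real counts of 0, 2 and 9 genes (highest 393, 1054 and 36), so chance cannot be excluded on days 2 and 3 and is 4 in 100 on day 5, and splits calling far more genes may point to a structure among the samples, which was not tested. Higher red cell and cell cycle transcripts at VarDR day 30, after lower red cell markers at day 3, would fit renewed erythropoiesis only weakly. The red cell list had camera adjusted p of 0.144 on day 3 and 0.0972 on day 30 with an estimated correlation, its medians shrank to −0.64 and 0.64 after quantile normalization, and Alas2 on day 3 to −0.22. Red cell indices would test it. Spiked-in RNA would settle whether most acute genes rose, which the deposited day 3 median of 1.20 cannot, as groups appear scaled apart.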
